A study of Homo sapiens with 12 samples.

How the data were processed

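Poly(A)-selected RNA was sequenced from DLD-1 cells, a human colorectal adenocarcinoma line, engineered to carry an auxin-inducible degron on SPT6 or on PAF1. The degron lets the plant receptor OsTIR1 mark the tagged protein for destruction once auxin is added, so the protein is removed while its mRNA is not targeted. There were 12 libraries in 6 groups of 2: SPT6-AID cells and PAF1-AID cells, each after 0, 2 or 6 h in 500 µM auxin. The labels number the SPT6-AID libraries 1 and 2 and the PAF1-AID libraries 3 and 4. They do not say whether these were separate cultures, so p-values measure only the spread between libraries, which may be technical.

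Per the labels' protocols, RNA was extracted on columns, poly(A) RNA was selected with a NEBNext module and libraries were made with a directional NEBNext kit. Per the submitters' processing notes, cutadapt 1.14, STAR 2.7.5 and featureCounts 2.0.0 were used, with the builds GRCh38 (human) and BDGP6 (fly). The deposited table holds whole-number read counts per gene for all 12 libraries, not normalized by the authors. The strand setting of the counting, the annotation release, and the amount and manner in which fly material was added are not given by the labels. Antisense genes, overlapping genes and near-identical copies (the SNORD3 genes, 5.8S rRNA copies, HSPA1A and HSPA1B, histone genes) are therefore uncertain. The table also has a gene length and a transcript length per gene, deposited by the authors.

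The table has 60666 human and 17807 fly gene rows, told apart by their identifiers, and every library column was mapped to 1 sample by its name. Total counts ran from 31957953 (SPT6-AID 6h replicate 2) to 115904780 (SPT6-AID 2h replicate 2), and fly counts from 1661945 to 5564723. No libraries of a group were copies of each other: chi-square per degree of freedom between them was 42.8 to 79.6. Gene positions and types came from GENCODE release 29 on GRCh38, matched by gene ID for 58420 rows holding 99.98% of human counts. The deposited gene length equalled the GENCODE 29 span for 75.8% of those rows, so the authors' release differed.

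Human genes passing edgeR's filterByExpr were kept (20791 genes) and scaled by TMM. A model of 6 group means over all 12 libraries was fitted, with 6 residual degrees of freedom, and contrasts were tested with edgeR's quasi-likelihood test. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. The comparisons were 2 and 6 h against 0 h in each line, 6 against 2 h in each line, the difference between the lines' responses at each time, and PAF1-AID against SPT6-AID at 0 h. The 31 gene lists, the comparisons, the rule for named genes and the alternative settings were fixed, except where an alternative is said to have been added later, before the data were examined. Lists were tested on log2 CPM (prior count 2) with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Genes named from each comparison with 0 h were the target gene, the 8 largest changes in each direction past the threshold (mean log2 CPM of at least 1, same direction in both libraries) and up to 4 members per list with the smallest p. For the other comparisons the 5 largest in each direction were taken. Other genes are stated to be chosen after their values were seen. Not every gene that met the rule is named.

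Correlations of fold changes are across genes, which are not independent replicates. Comparisons within a line share their 0 h libraries, so 20 simulations of unchanged groups gave the value that sharing alone produces. The alternatives were DESeq2's size factors, total counts, fly totals as library sizes, no filter on low counts, a mean of at least 1 CPM, DESeq2's Wald test, limma-voom, a fit of the line alone, the replicate number as a block, a prior count of 2, and leaving out each library. Keeping the genes of the full fit while leaving out a library was added after the values were seen. Where a leave-out left 1 library in a group, it was assumed to vary like the others. Groups of 2 are too small for a test of single outlying libraries, and other splits of the samples were not made.

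The edgeR step was tested on simulated data drawn for 20791 genes from the real means, library sizes and dispersions, with 200 genes changed. These were taken from genes with a mean above 1 CPM. Far more genes passed in the real 6 h comparisons, which makes the adjusted threshold easier to reach, so the simulated shares do not give the power there. For SPT6-AID 6h against 0h it recovered 6.0% of genes changed 1.5-fold, 36.0% at 2-fold, 80.0% at 4-fold and 100.0% at 8-fold, with 7 false calls among 120. For PAF1-AID 2h against 0h the shares were 2.0%, 36.0%, 94.0% and 98.0%, with 5 false calls among 123. The list test called a list of 30 genes raised 1.5-fold in both simulations and did not call a flat list. Simulated genes varied independently, so this does not check the list test where genes of a list vary together. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.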

Results

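The series asked how transcription responds in the first hours after SPT6, a histone chaperone that travels with RNA polymerase II, or PAF1, a subunit of the PAF1 elongation complex, is removed from cells. Read counts per gene were measured in 12 libraries of DLD-1 colorectal cancer cells: 2 libraries each of SPT6-AID and PAF1-AID cells at 0, 2 and 6 h of auxin. Totals per library were 31957953 to 115904780 counts. No auxin-treated cells without a tagged protein were among the samples, so every change from 0 h combines depletion with any effect of auxin.

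The degron acts on protein, which was not measured, so the targeted genes' mRNA does not check depletion. SUPT6H, which encodes SPT6 (ENSG00000109111, GRCh38 chromosome 17, 28662091 to 28702684), was at 498 ± 3.66 CPM (SD, n = 2) at 0 h in SPT6-AID cells, 515 ± 8.02 at 2 h and 553 ± 5.69 at 6 h. Its log2 fold changes of 0.05 and 0.15 did not pass the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1 and 0.349). PAF1 (ENSG00000006712, chromosome 19, 39385852 to 39391195) was at 128.4 ± 3.596 CPM at 0 h in PAF1-AID cells, 127.0 ± 3.618 at 2 h and 116.4 ± 0.679 at 6 h, with adjusted p of 1 and 0.512 by the same edgeR test.

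**Figure D1:**
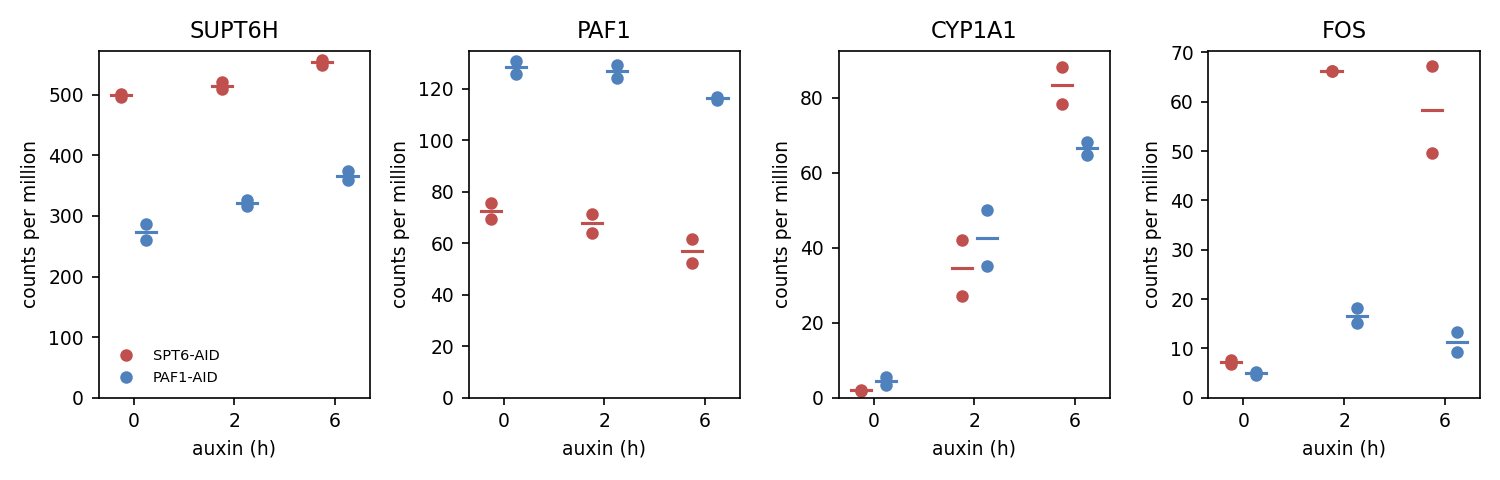
CPM of SUPT6H, PAF1, CYP1A1 and FOS in each of the 12 libraries (points) and the mean of each group (lines) against hours of auxin, on linear axes from 0. The mRNA of each depleted protein stays near its 0 h level in its own line, while CYP1A1 goes from 2.00 to 83.3 CPM in SPT6-AID cells and from 4.54 to 66.5 CPM in PAF1-AID cells by 6 h.

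After 2 h without SPT6, a small set of transcripts rose sharply and a larger set fell. The U3 small nucleolar RNA genes SNORD3B-1, SNORD3B-2 and SNORD3A, which guide early cleavage of ribosomal RNA precursors, rose by 4.91 ± 0.27 (log2 ± SE), 4.44 ± 0.30 and 4.06 ± 0.27. CYP1A1, a cytochrome P450 that is the classic target of the aryl hydrocarbon receptor (chromosome 15, 74719542 to 74725610), rose by 4.11 ± 0.31, and FOS, an AP-1 transcription factor of the immediate early response, rose by 3.18 ± 0.22. A 5.8S rRNA gene (3.05 ± 0.22) and MIR663AHG (3.96 ± 0.63) rose with them. Among the genes that fell were DUSP6, a phosphatase that restrains ERK signalling (-1.89 ± 0.18), AXIN2, a feedback inhibitor of WNT signalling (-1.66 ± 0.20), DDIT3, a stress-response transcription factor (-1.83 ± 0.27), and OTX1 (-1.74 ± 0.32).

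Zinc finger genes were 23 of the 96 genes that fell at 2 h. Of 371 measured ZNF genes, 23 fell and 0 rose (110 fell when adjusted over the list alone), including ZNF443 (-1.84), ZNF551 (-1.78), ZNF526 (-1.59) and ZNF484 (-1.58). The list median was -0.49 (camera adjusted p = 1.62e-35, adjusted p = 0.0868 with an estimated correlation). Of 21 WNT targets, AXIN2 and BMP4 (-1.09) fell, and 9 did when adjusted over the list alone (median -0.28, camera adjusted p = 4.46e-06, adjusted p = 0.0804 with an estimated correlation). Of 18 snoRNA host genes, SNHG15 (-1.27) and SNHG7 (-0.89) fell, or 6 adjusted over the list alone (camera adjusted p = 1.52e-06, adjusted p = 0.285 with an estimated correlation). The 37 immediate early genes went both ways: FOS and GADD45B (1.24) rose and 4 fell, DUSP6 and DUSP5 (-0.97) among them, with 3 higher and 8 lower when adjusted over the list alone (median -0.29, camera adjusted p = 0.00253, adjusted p = 0.146 with an estimated correlation).

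In all, 114 of 20791 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at 2 h of SPT6 depletion, 18 higher and 96 lower. The count is fragile: it was 7 to 10 without any 1 of the 4 SPT6-AID libraries at 0 h and 2 h and 48 to 53 without any 1 of the 6 PAF1-AID libraries. It was 8 in SPT6-AID libraries alone, 66 with total counts, 380 with no filter and 470 by DESeq2, and scaling by fly reads left 10 higher and 23 lower. With the replicate number as a block many more genes were called, all of the main ones included. That count is given with the processing, since the labels do not say what the number stands for.

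By 6 h of SPT6 depletion the response was broad. SNORD3B-1 (5.28 ± 0.27), SNORD3B-2 (4.74 ± 0.31), SNORD3A (4.39 ± 0.27), CYP1A1 (5.38 ± 0.32), the 5.8S rRNA gene (4.70 ± 0.24) and MIR663AHG (5.92 ± 0.68) were still raised, and MIR3648-2 rose by 6.69 ± 1.88, with replicates at 3.55 and 6.54. Among genes with a mean log2 CPM of at least 1, the steepest falls were in CCDC71 (-3.15 ± 0.24), CSTF1, a subunit of the mRNA 3' end cleavage stimulation factor (-3.02 ± 0.27), RPP38, a protein of RNase P (-2.89 ± 0.31), KDM8 (-2.84 ± 0.37), MTFR2 (-2.80 ± 0.39), the arginine methyltransferase PRMT6 (-2.69 ± 0.31), KLHL9 (-2.61 ± 0.19) and ETAA1, an activator of ATR (-2.52 ± 0.25).

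Immediate early genes rose at 6 h: 19 of 37 rose and 2 fell (21 and 2 adjusted over the list alone), among them GADD45B (2.49), JUNB (2.46), FOS (3.0) and JUN (1.61), with a median of 0.83, or 0.40 under fly scaling (camera adjusted p = 4.06e-06, adjusted p = 0.108 with an estimated correlation). Of 10 measured aryl hydrocarbon receptor targets 5 rose and 1 fell (6 and 1 adjusted over the list alone), with CYP1B1 at 2.28, CYP1A2 at 2.40 and TIPARP at 1.30 (camera adjusted p = 0.00576, adjusted p = 0.194 with an estimated correlation). Of 24 p53 targets 2 rose, CDKN1A (1.78) and SPATA18 (4.78), and 7 fell, MDM2 (-1.61) and XPC (-0.97) among them (2 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.146). SPATA18 missed the rule for the largest changes (mean log2 CPM of at least 1, same direction in both libraries), so its size is uncertain. HSPA1A (1.35) and HSPA1B (1.77), near-identical heat shock genes, rose, and HSPA8 fell (-1.25).

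Some cell division and DNA repair genes fell at 6 h. Of 28 G2/M genes 18 fell and 0 rose (21 adjusted over the list alone), including CENPA (-2.10), AURKA (-1.75), TTK (-1.42) and BUB1B (-1.25), with camera adjusted p = 6.91e-07 and adjusted p = 0.316 with an estimated correlation. Of 23 DNA repair genes 13 fell (15 adjusted over the list alone), including FANCM (-2.16), PALB2 (-1.77), BRCA2 (-1.33) and BARD1 (-1.30), with camera adjusted p = 2.45e-05 and adjusted p = 0.316 with an estimated correlation. Ribosome biogenesis genes such as GRWD1 (-1.92) and POLR1B (-1.63) fell in 13 of 32 cases, also 13 adjusted over the list alone (camera adjusted p = 0.000372, adjusted p = 0.531 with an estimated correlation). Among 23 splicing regulators and genes regulated by nonsense-mediated decay 13 fell and 1 rose (14 and 1 adjusted over the list alone), RBM39 (-1.40) and CLK4 (-1.73) among the former (camera adjusted p = 3.34e-05, adjusted p = 0.108 with an estimated correlation). ZNF genes fell in 164 of 371 cases and rose in 16 (184 and 20 adjusted over the list alone), with camera adjusted p = 9.6e-11 and adjusted p = 0.306 with an estimated correlation.

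The elongation machinery itself was among the transcripts that fell. LEO1 (-1.31 ± 0.16), CDC73 (-1.05 ± 0.18) and RTF1 (-0.77 ± 0.17), subunits of the PAF1 complex, fell at 6 h of SPT6 depletion, while CTR9 (0.54 ± 0.13) rose. PAF1 itself was at -0.35 ± 0.12 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0542). Over the list alone 4 of the 6 subunits were lower and 1 higher, and the list as a whole did not pass (camera adjusted p = 0.148). Of 29 pausing and elongation factors 11 fell and 0 rose (12 adjusted over the list alone), including IWS1, an SPT6 partner (-1.74), MEPCE (-1.58), CDK12 (-1.42) and NELFA (-1.40), with camera adjusted p = 0.00806 and adjusted p = 0.316 with an estimated correlation.

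Of 2902 long non-coding genes 578 rose and 103 fell at 6 h, and the others did not pass. Of 483 antisense genes 98 rose and 12 fell (97 and 11 adjusted over the list alone), including ADAMTSL4-AS2 (5.09) and RUFY1-AS1 (4.05), with camera adjusted p = 6.44e-07 and adjusted p = 0.247 with an estimated correlation. ADAMTSL4-AS2 missed the rule for the largest changes (mean log2 CPM of at least 1, same direction in both libraries), so its size is uncertain. Of 334 LINC genes 64 rose and 14 fell (62 and 14 adjusted over the list alone), including LINC00672 (3.49) and LINC00899 (2.14), with camera adjusted p = 2.58e-05 and adjusted p = 0.234 with an estimated correlation. Against protein-coding genes of the same mean expression, however, long non-coding genes had no excess (median difference -0.00217, against 0.64 without matching). Under fly scaling the median was 0.11 for antisense and 0.14 for LINC genes, against 0.55 and 0.56 with TMM. Antisense counts are also uncertain because the counting strand is not given. The 84 ribosomal protein genes had a median of 0.36 with 1 gene higher and 2 lower, a median that becomes -0.10 under fly scaling (camera adjusted p = 0.000372, adjusted p = 0.709 with an estimated correlation).

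Mitochondrially encoded genes were higher at 6 h in SPT6-AID cells, where 5 of 13 rose (11 adjusted over the list alone), such as MT-CO1 at 0.66 and MT-ND4 at 0.67 (camera adjusted p = 0.000372, adjusted p = 0.426 with an estimated correlation). The list median was 0.66 with TMM and 0.22 under fly scaling. Their share of human counts was 2.27% and 2.32% at 0 h and 3.63% and 3.68% at 6 h. Of 5 measured blood cell markers, CD14 (1.76) and CD79A (1.57) rose, both also when adjusted over the list alone (camera adjusted p = 0.0389, adjusted p = 0.287 with an estimated correlation).

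At 6 h of SPT6 depletion 5230 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 1821 higher and 3409 lower, of which 3043 changed at least 2-fold. The count was 3344 and 3206 without SPT6-AID 0h replicates 1 and 2 and 3189 without SPT6-AID 6h replicate 2. With fly reads as the scale, the median log2 change of all genes was -0.39, against 0.04 with TMM, and the calls became 958 higher and 5842 lower.

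**Figure D2:**
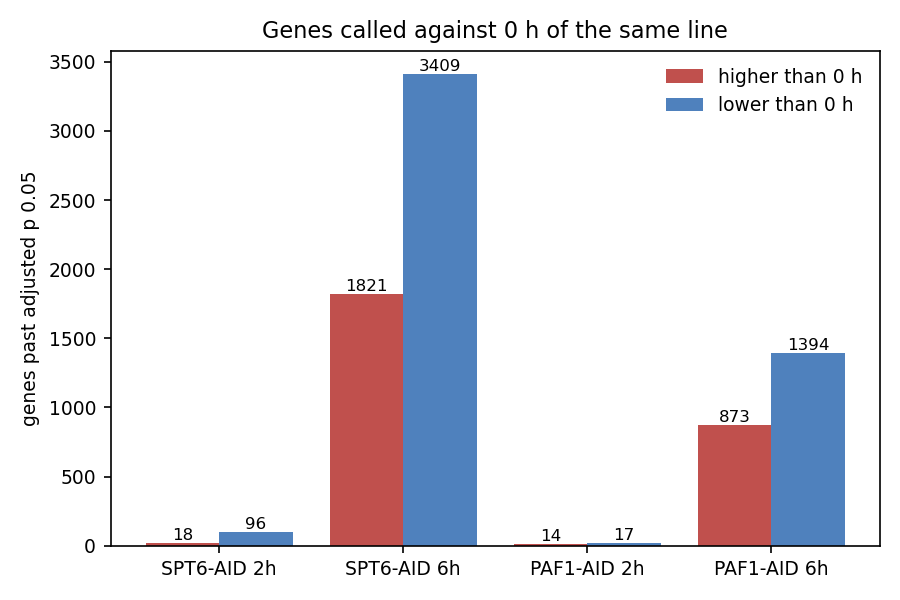
Number of genes past an adjusted p of 0.05 (edgeR quasi-likelihood test) against 0 h of the same line, higher (red) and lower (blue), on a linear axis from 0. SPT6-AID cells went from 114 genes at 2 h to 5230 at 6 h, and PAF1-AID cells from 31 to 2267.

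After 2 h without PAF1, CYP1A1 (3.23 ± 0.29), SPEF1 (2.35 ± 0.31), the 5.8S rRNA gene (1.80 ± 0.22), TIPARP, an aryl hydrocarbon receptor target (1.76 ± 0.22), and FOS (1.74 ± 0.22) rose, as did PHLDA2 (1.01 ± 0.12) and PPP1R15A (0.96 ± 0.14). PPP1R10, a phosphatase 1 regulatory subunit that acts in transcription termination, fell most among genes with a mean log2 CPM of at least 1 (-2.17 ± 0.21; chromosome 6, 30600400 to 30618612), followed by DDIT3 (-1.84 ± 0.27), ETAA1 (-1.81 ± 0.24), BCDIN3D (-1.62 ± 0.25) and the general transcription factor GTF2E1 (-1.55 ± 0.22). ZBED5 (-1.46) and HRH1 (-1.27) fell too.

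Of 371 ZNF genes 2 fell and 1 rose at 2 h (30 and 2 adjusted over the list alone), ZNF689 at -1.05 and ZNF574 at 0.78 among them (median -0.29, camera adjusted p = 1.86e-14, adjusted p = 0.339 with an estimated correlation). The WNT target RNF43 fell (-1.22), 1 of 21 or 5 adjusted over the list alone (camera adjusted p = 0.0149, adjusted p = 0.321 with an estimated correlation). Aryl hydrocarbon receptor targets rose in 2 of 10 cases, 3 adjusted over the list alone (camera adjusted p = 0.000889, adjusted p = 0.13 with an estimated correlation). None of the 13 mitochondrially encoded genes passed over all genes, and 7 were higher adjusted over the list alone (median 0.60, or 0.38 under fly scaling, camera adjusted p = 1.57e-08, adjusted p = 0.376 with an estimated correlation). Their share of human counts at 0 h was 1.54% in PAF1-AID replicate 3 and 2.05% in replicate 4, against 2.52% and 2.41% at 2 h.

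In total 31 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at 2 h of PAF1 depletion, 14 higher and 17 lower. The count was 0 without PAF1-AID 0h replicate 3 or 2h replicate 4 (1313 and 1084 at an unadjusted p under 0.05), 1 without PAF1-AID 0h replicate 4 or 2h replicate 3, 6 to 8 without an SPT6-AID library of 0 h or 2 h, and 11 and 9 without PAF1-AID 6h replicates 3 and 4. With PAF1-AID libraries alone it was 0 (1678 at an unadjusted p under 0.05), with fly scaling 1 higher and 1 lower, with no filter 274 and by DESeq2 248. The replicate number as a block gave many more calls, all of the main ones included, and its count is given with the processing.

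At 6 h of PAF1 depletion, among genes with a mean log2 CPM of at least 1, PPFIA4, a liprin scaffold protein (3.95 ± 0.46; chromosome 1, 203026498 to 203078740), CYP1A1 (3.87 ± 0.30), MIR663AHG (3.77 ± 0.66), SPEF1 (3.16 ± 0.31), LINC00672 (2.64 ± 0.40), SELPLG (2.50 ± 0.30), ADAM11 (2.46 ± 0.30) and SNAI1, a repressor of epithelial genes (2.45 ± 0.30), rose most. ANKRD1, a YAP target (-2.82 ± 0.28), the interferon regulatory factor IRF2 (-2.73 ± 0.22), KDM8 (-2.40 ± 0.34), SMG9, of nonsense-mediated decay (-2.36 ± 0.30), MAGEF1 (-2.24 ± 0.14), RAB23 (-2.17 ± 0.35), ZNF616 (-2.14 ± 0.33) and RAD52, a recombination protein (-2.14 ± 0.28), fell most.

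In PAF1-AID cells at 6 h, some repair and mitotic genes fell. Of 23 DNA repair genes 6 fell (9 adjusted over the list alone), including BRCA2 (-1.29), PALB2 (-1.25) and FANCM (-0.91), with camera adjusted p = 0.000385 and adjusted p = 0.714 with an estimated correlation. Of 28 G2/M genes 8 fell (10 adjusted over the list alone), including CENPA (-1.36) and AURKA (-1.12), with camera adjusted p = 0.00196 and adjusted p = 0.733 with an estimated correlation. ZNF genes fell in 75 of 371 cases and rose in 19 (101 and 26 adjusted over the list alone), with camera adjusted p = 0.000475 and adjusted p = 0.733 with an estimated correlation. CTR9 rose (0.87 ± 0.13) and was the 1 subunit of the PAF1 complex to pass, also adjusted over the list alone.

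Intestinal epithelial markers rose in 4 of 19 cases (5 adjusted over the list alone): ELF3 at 1.02, LGALS4 at 2.18, CLDN4 at 0.65 and CDX2 at 0.75. Their median of 0.28 becomes -0.09 under fly scaling (camera adjusted p = 0.0175, adjusted p = 0.301 with an estimated correlation). Aryl hydrocarbon receptor targets rose in 3 of 10 cases (4 adjusted over the list alone), CYP1A1, TIPARP (1.36) and CYP1B1 (1.34), with camera adjusted p = 0.00664 and adjusted p = 0.301 with an estimated correlation. Immediate early genes split, with 10 of 37 higher and 5 lower (12 and 6 adjusted over the list alone), JUNB (1.25) and IER3 (-1.29) among them, and the list did not pass (camera adjusted p = 0.127). Of 13 mitochondrially encoded genes 0 passed over all genes and 9 were higher adjusted over the list alone (camera adjusted p = 0.000385, adjusted p = 0.714 with an estimated correlation). The list median was 0.67 with TMM and 0.30 under fly scaling. Their share of human counts went from 1.54% at 0 h to 2.95% at 6 h in replicate 3, but only from 2.05% to 2.09% in replicate 4.

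At 6 h of PAF1 depletion 2267 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 873 higher and 1394 lower. Without PAF1-AID 0h replicates 3 and 4 the count was 942 and 987, and without PAF1-AID 6h replicates 3 and 4 it was 362 and 1185. With fly scaling the median of all genes was -0.37, against 0.02 with TMM, and the calls were 296 higher and 2865 lower.

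**Figure D3:**
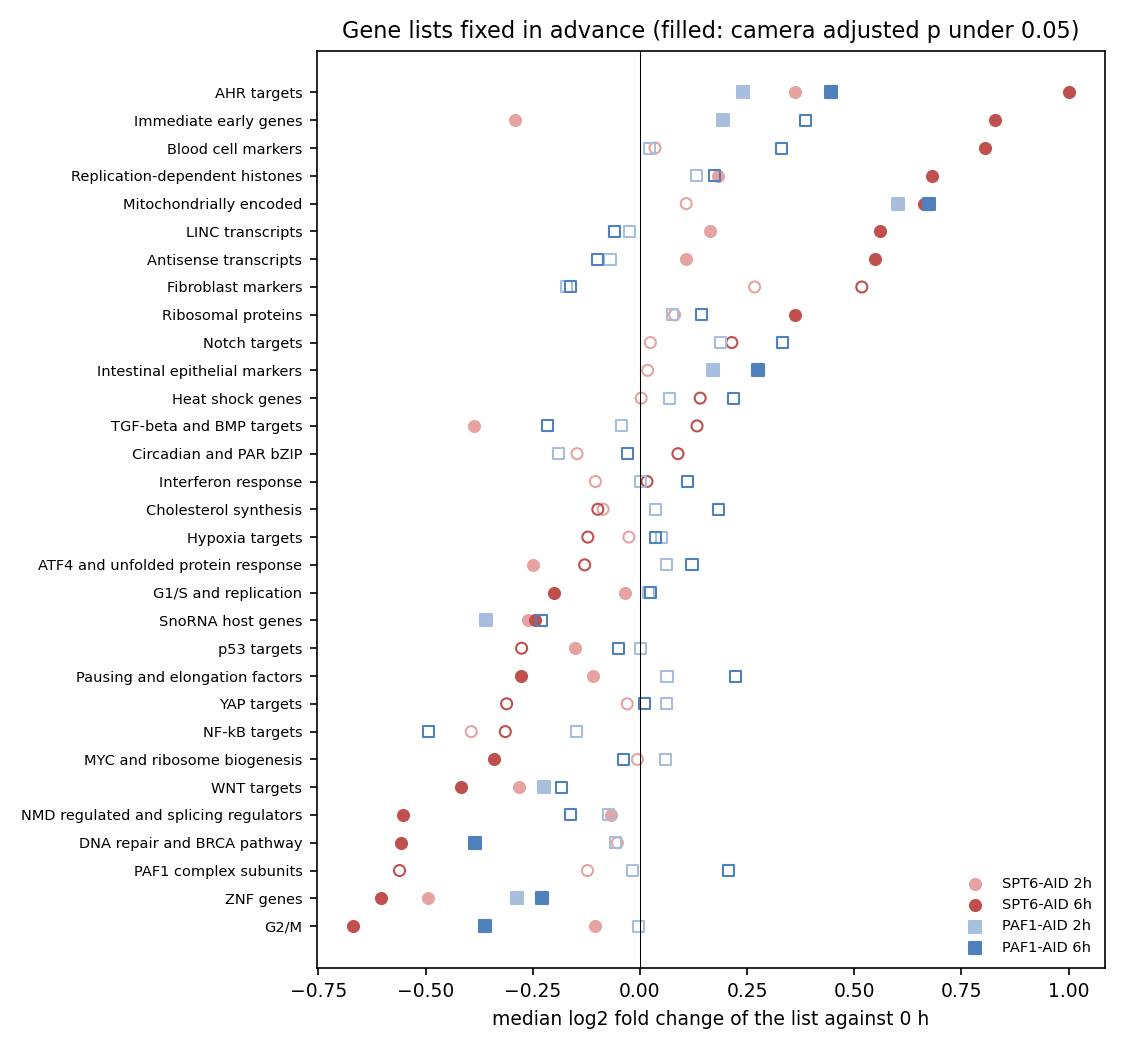
Median log2 fold change against 0 h of the 31 gene lists (rows) in the 4 comparisons with 0 h (circles SPT6-AID, squares PAF1-AID), filled where camera's adjusted p with its preset correlation was under 0.05 and open otherwise. With an estimated correlation 0 of the lists passed, and G2/M genes have the lowest median in SPT6-AID cells at 6 h (-0.67) and aryl hydrocarbon receptor targets the highest (1.00).

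Between 2 and 6 h of SPT6 depletion, CDKN2B, a cyclin-dependent kinase inhibitor (3.44 ± 0.83), LTBP2 (2.82 ± 0.34), TENT5C (2.79 ± 0.33), the early growth response factor EGR3 (2.69 ± 0.42) and RUFY1-AS1 (2.69 ± 0.36) rose. RAD52 (-2.40 ± 0.28), KDM8 (-2.32 ± 0.36), CCDC71 (-2.28 ± 0.23), CSTF1 (-2.24 ± 0.26) and GOLPH3 (-2.11 ± 0.22) fell. Immediate early genes rose in 24 of 37 cases with 0 lower (26 and 0 adjusted over the list alone), the 1 list that passed with an estimated correlation (median 0.99, camera adjusted p = 4.38e-14, adjusted p = 0.0125 with an estimated correlation). The edgeR quasi-likelihood test called 3273 genes, 1107 higher and 2166 lower. That count was 1718 and 1119 without SPT6-AID 2h replicates 1 and 2, 1293 without SPT6-AID 6h replicate 2 and 1940 in SPT6-AID libraries alone.

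Between 2 and 6 h of PAF1 depletion, PPFIA4 (2.30 ± 0.42), ADAM11 (1.95 ± 0.29), EFCAB12 (1.76 ± 0.24), the mRNA export factor NXF1 (1.28 ± 0.12) and KLHL15 (1.12 ± 0.14) rose. IRF2 (-1.99 ± 0.21), LRRC20 (-1.62 ± 0.25), SMG9 (-1.62 ± 0.30), YEATS4 (-1.60 ± 0.29) and the nuclear receptor NR2C2 (-1.54 ± 0.26) fell. The edgeR quasi-likelihood test called 182 genes, 60 higher and 122 lower. The count was 267 without SPT6-AID 6h replicate 1 or 2 and 0 to 4 without any 1 of the other 10 libraries, those of the other line included. It was 0 without PAF1-AID 2h replicate 3 or 6h replicate 3 (1928 and 1748 at an unadjusted p under 0.05). It was 79 with total counts, 101 in PAF1-AID libraries alone, 663 with no filter and 781 by DESeq2, and fly scaling called 0, with 2502 genes at an unadjusted p under 0.05.

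The lines were compared directly by testing the difference between their responses. SNORD3B-2 (4.44 ± 0.41), SNORD3B-1 (4.31 ± 0.36) and SNORD3A (3.56 ± 0.36) rose more in SPT6-AID cells at 2 h, and ZNF551 (-2.39 ± 0.31), ZNF597 (-2.01 ± 0.23), ITPRIP (-1.43 ± 0.19) and ZNF574 (-1.31 ± 0.17) were lower there; these were all 7 genes called by the edgeR quasi-likelihood test. Without PAF1-AID 2h replicate 4 the test called 0 (459 at an unadjusted p under 0.05), without any 1 other library of 0 h or 2 h it called 2 or 3, and without PAF1-AID 6h replicate 3 or 4 it called 4. DESeq2 called 48 and limma-voom 4, and fly scaling left 4, 3 higher and 1 lower. At 6 h the SNORD3 genes differed by 4.0 to 4.79. EGR1, an immediate early transcription factor, went in opposite directions: it rose by 1.34 ± 0.36 in SPT6-AID cells and fell by 1.99 on the log2 scale in PAF1-AID cells, a difference of 3.33 ± 0.52. EGR3 differed by 3.45 ± 0.58. URB2, a ribosome biogenesis factor (-2.39 ± 0.30), TNK1 (-2.27 ± 0.36), KIAA1586 (-2.24 ± 0.23), DCAF16 (-2.18 ± 0.33) and ZNF695 (-2.11 ± 0.33) were lower in SPT6-AID cells.

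LEO1 and RTF1 of the PAF1 complex, which fell without SPT6, were at 0.16 and 0.25 without PAF1 and did not pass there, and their responses differed by -1.47 ± 0.22 and -1.01 ± 0.23 (edgeR quasi-likelihood test, adjusted p = 0.013 and 0.0424), 2 of the 6 subunits (list camera adjusted p = 0.00281, adjusted p = 0.135 with an estimated correlation). Their difference values were looked up after the subunits' changes at 6 h had been seen. Over all genes 778 differed at 6 h, 129 higher and 649 lower in SPT6-AID cells, by the same test. Leaving out 1 library gave 30 (PAF1-AID 6h replicate 4) to 1061 genes. By left-out library the count was 172 and 60 (SPT6-AID 0h replicates 1 and 2), 479 (SPT6-AID 2h replicate 2), 153 (SPT6-AID 6h replicate 2), 52 and 185 (PAF1-AID 0h replicates 3 and 4), 418 and 420 (PAF1-AID 2h replicates 3 and 4) and 234 (PAF1-AID 6h replicate 3). Total counts gave 223 and fly scaling 16, 7 higher and 9 lower. With the replicate number as a block, many more genes were called for the differences at 2 h and 6 h. The same held at 6 h against 0 h and at 6 h against 2 h in each line. All of the main calls were included, and the counts are given with the processing.

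The responses of the lines were correlated across genes, which are not independent replicates. Pearson's r was 0.35 at 2 h (Spearman's rho 0.37) and 0.63 at 6 h (rho 0.54). The 2 h value depended on the filter: r was 0.0691 with no filter and 0.598 with a mean of at least 1 CPM. With an SPT6-AID library left out, r was 0.208 and 0.209 (0h replicates 1 and 2) and 0.216 and 0.192 (2h replicates 1 and 2). With a PAF1-AID library left out, it was 0.217 (0h replicate 4) and 0.163 and 0.174 (2h replicates 3 and 4). Leaving out a library also reran the filter, which then kept 21734 to 22044 genes, so library and filter are not told apart. Over pairings of single replicates with the 20791 genes of the full fit, r at 2 h was 0.247 to 0.291. With no filter the 6 h value was 0.264. At 6 h 478 genes were higher in both lines where independent lists would share 76.5, and 1038 were lower in both where 229 would be shared. Opposite calls numbered 5 and 28. Within a line, r between 2 h and 6 h was 0.69 for SPT6-AID and 0.68 for PAF1-AID, where unchanged groups against shared 0 h libraries gave 0.49 and 0.51. Without SPT6-AID 2h replicate 2 the former was 0.426. The covariances were 0.396 and 0.331 against simulated values of 0.112 and 0.121. The 2 libraries at 0 h were not split between the comparisons, so part of the excess may come from sharing them.

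**Figure D4:**
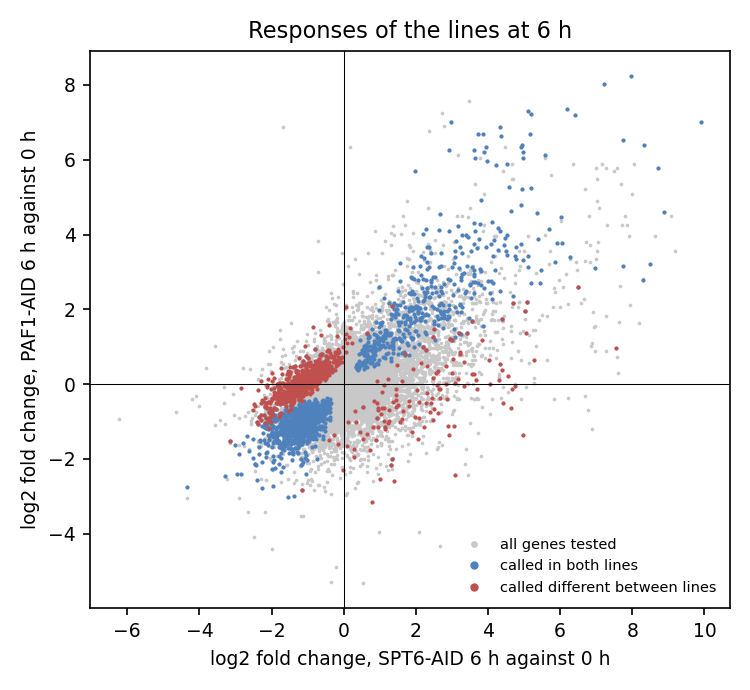
Log2 fold change at 6 h against 0 h in SPT6-AID cells (horizontal) and PAF1-AID cells (vertical) for all 20791 genes (grey), those called in both lines (blue) and the 778 whose responses differed between lines (red, drawn on top). Most of the latter, 649, lie toward lower values in SPT6-AID cells.

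Longer genes were lower in SPT6-AID cells. Spearman's rho between gene length and log2 fold change, across genes, was -0.15 at 2 h and -0.23 at 6 h in SPT6-AID cells, and -0.03 and -0.09 in PAF1-AID cells. Among the 13663 protein-coding genes alone it was -0.09 and -0.20 in SPT6-AID and -0.01 and -0.06 in PAF1-AID cells. At 2 h of SPT6 depletion it was -0.0885 without SPT6-AID 0h replicate 1, -0.0556 without 2h replicate 2 and -0.0683 with no filter, and at 6 h -0.105 with no filter. At 6 h of SPT6 depletion the 4159 genes with the shortest span had a median of 0.27 and the 4158 with the longest a median of -0.19, and 26.0% of the latter were called lower. For PAF1-AID at 2 h the sign turned without PAF1-AID 0h replicate 3 (0.0371) and without PAF1-AID 2h replicate 4 (0.0109). These leave-outs reran the filter too, so library and filter are not told apart. With the 20791 genes of the full fit, single replicates at 2 h gave -0.16 to -0.10 in SPT6-AID and -0.07 to 0.02 in PAF1-AID cells.

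Before auxin, the lines differed at few genes. S100A4, a calcium-binding protein linked to motility, was higher in PAF1-AID cells (1.81 ± 0.22). PLXNA2 (-3.19 ± 0.41), the collagen receptor subunit ITGA2 (-1.38 ± 0.14), ARSD (-1.08 ± 0.13), CLIC5 (-1.06 ± 0.12) and SUPT6H (-0.86 ± 0.11) were lower. PAF1 was at 0.82 ± 0.12 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0869). The test called 7 genes. It called 0 without any 1 library of 0 h or 6 h (909 to 1661 at an unadjusted p under 0.05), 1 without PAF1-AID 2h replicate 3 or 4, 3 without SPT6-AID 2h replicate 1 or 2, 0 with total counts and with fly scaling (1362 and 1056 at an unadjusted p under 0.05), 317 with no filter and 79 by DESeq2.

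Fly reads relative to human reads were compared over time in auxin. Per 100 human reads there were 4.49 ± 0.00764 (SD, n = 2) fly reads at 0 h, 4.92 ± 0.169 at 2 h and 6.16 ± 0.712 at 6 h in SPT6-AID cells, and 4.35 ± 0.352, 4.80 ± 0.0179 and 5.27 ± 0.141 in PAF1-AID cells. The tests of fly genes were added after the counts were seen. Among 7258 fly genes the edgeR quasi-likelihood test called 24 for SPT6-AID 6h and 11 for PAF1-AID 6h against 0h. How the fly material was added is not stated, so whether the ratio reflects RNA per cell was not determined.

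**Figure D5:**
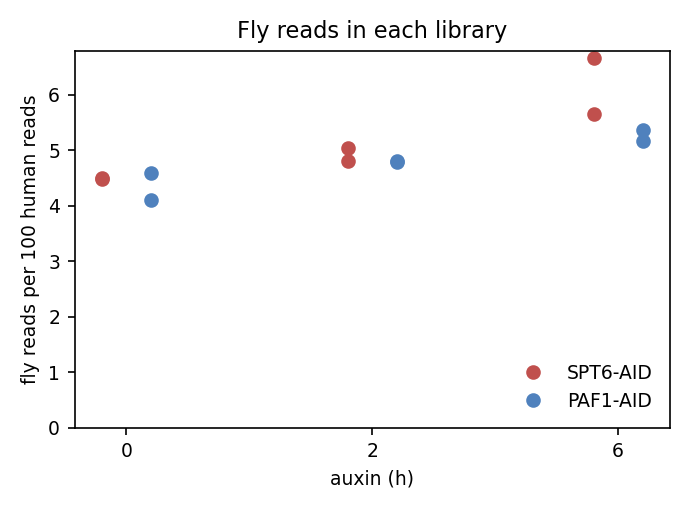
Fly reads per 100 human reads in each of the 12 libraries against hours of auxin, on a linear axis from 0. Values run from 4.10 in a PAF1-AID library at 0 h to 6.66 in an SPT6-AID library at 6 h.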

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

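The tests on aryl hydrocarbon receptor targets and the sum over rRNA genes were chosen only after the result was seen. The other tests in this part were set beforehand. The genes and lists of the next 2 paragraphs were picked out because the change in SPT6-AID cells differed from that in PAF1-AID cells, tested as the difference between the responses with edgeR's quasi-likelihood test for genes and camera for lists.

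At 2 h the responses of 7 genes differed: SNORD3B-2 (4.44, SPT6-AID minus PAF1-AID), SNORD3B-1 (4.31), SNORD3A (3.56), ZNF551 (-2.39), ZNF597 (-2.01), ITPRIP (-1.43) and ZNF574 (-1.31). At 6 h 778 differed, among them SNORD3B-2 (4.79), SNORD3B-1 (4.64), SNORD3A (4.0), EGR3 (3.45), EGR1 (3.33), URB2 (-2.39), TNK1 (-2.27), KIAA1586 (-2.24), DCAF16 (-2.18) and ZNF695 (-2.11).

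For gene lists at 2 h the median differences past camera's threshold were -0.33 for immediate early genes, -0.17 for p53 targets, -0.16 for WNT targets, -0.15 for ATF4 and unfolded protein response genes, -0.10 for cholesterol synthesis, -0.12 for intestinal markers, 0.21 for replication-dependent histones, -0.47 for mitochondrially encoded genes, -0.11 for ZNF genes, 0.20 for antisense genes and 0.23 for LINC genes. With fly scaling the 2 h median was -0.20 for immediate early genes, 0.33 for histones, 0.30 for antisense genes, 0.33 for LINC genes, -0.39 for mitochondrially encoded genes, -0.01 for cholesterol synthesis, -0.02 for intestinal markers, -0.00230 for ZNF genes, -0.02 for WNT targets, -0.05 for p53 targets and -0.05 for ATF4 and unfolded protein response genes. At 6 h the medians were -0.59 for PAF1 complex subunits, -0.49 for pausing and elongation factors, 0.64 for immediate early genes, -0.36 for cholesterol synthesis, -0.30 for ribosome biogenesis, -0.34 for G1/S genes, -0.34 for G2/M genes, -0.20 for splicing regulators and genes regulated by nonsense-mediated decay, 0.20 for ribosomal proteins (0.10 with fly scaling), 0.53 for histones, -0.32 for ZNF genes, 0.60 for antisense genes and 0.49 for LINC genes. With an estimated correlation camera's adjusted p was at least 0.0831 for each of these lists at 2 h and at least 0.135 at 6 h.

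The SNORD3 genes, 5.8S rRNA, MIR663AHG and MIR3648-2 rose in SPT6-AID cells at 6 h, with a median of 5.01 over 6 genes. For the SNORD3 genes, reads moving among near-identical copies are argued against: the summed CPM of 60 SNORD3 and U3 genes rose by 4.43 on the log2 scale (replicate SD 0.18), from 2.41 to 52.3 CPM, against 3.69 and 4.21 CPM in PAF1-AID cells. For 5.8S rRNA, the summed CPM of all genes typed as rRNA or rRNA pseudogene argues against it too. In SPT6-AID cells that sum was 9.01 and 7.97 at 0 h and 207 and 202 at 6 h. No copies of MIR663AHG or MIR3648-2 were summed, so for those genes the explanation was not tested. Carry-over of RNA without poly(A) tails may contribute and stays open. Of 49 other such RNAs 7 were measured well enough to test, with a median of 0.60 and a 95% bootstrap interval of -0.06 to 2.58, too wide to decide: the abundant RN7SL1 and RN7SL3 were at -0.03 ± 0.46 and -0.06 ± 0.25, while scarce RNU5A-1 was at 5.84 ± 1.25. Loss of SPT6 remains an untested biological explanation, but part of the pattern was also seen in PAF1-AID cells at 6 h, where MIR663AHG rose by 3.77 and 5.8S rRNA by 2.16, and MIR3648-2 was at 3.30 without passing.

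Some aryl hydrocarbon receptor targets rose in both lines at 6 h: 5 of 10 rose and 1 fell in SPT6-AID cells, and 3 of 10 rose in PAF1-AID cells. Over all 10 targets the medians were 1.00 in SPT6-AID and 0.45 in PAF1-AID cells, and the list did not pass with an estimated correlation. Over the 3 targets picked because they were called in both lines, the medians were 2.28 and 1.36. Scaling between libraries is not excluded as a contributor: the smallest median over 3 scalings was 0.99 ± 0.30 for the 3 targets (PAF1-AID cells, fly scaling), and over all 10 targets the medians under fly scaling were 0.60 and 0.05. Auxin itself may also raise them, and with no auxin-treated cells lacking a degron, auxin and depletion cannot be told apart. The response of CYP1A1 was 1.51 ± 0.39 larger in SPT6-AID cells, a difference that did not pass (edgeR quasi-likelihood test, adjusted p = 0.0644).

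Long non-coding genes were higher than protein-coding genes in SPT6-AID cells at 6 h, by a median of 0.64. The excess over coding genes of the same mean expression was -0.00217 (SD 0.083), so coding genes of similar expression rose as much. In PAF1-AID cells at 6 h the long non-coding median was -0.03, with 138 genes higher and 103 lower. Its replicates were at -0.14 and 0.13, and coding genes with several exons had a median of -0.004. This argues against low expression alone as the source. The excess over coding genes of the same length was 0.46 (SD 0.15), and the 518 non-coding genes over 10 kb from any coding gene had a median of 0.31 (SD 0.10), so neither gene length nor reads of nearby genes could be decided. A biological explanation beyond SPT6 loss was not tested.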

How the results depend on the processing

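Keeping the genes of the full fit while leaving out a library was tried only after the leave-out values were seen. In the leave-outs given here the filter was rerun and kept 21734 to 22044 genes, against 20791 in the full fit. Library and filter thus changed together. For the gene counts, leave-outs that kept the 20791 genes of the full fit gave nearly the same numbers. This argues against the filter as the source of the moves in those counts. Where no cause is given, the cause was not tested.

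Named genes mostly kept their direction and side of the threshold: 312 of 316 with DESeq2, 313 with DESeq2's size factors, 306 with limma-voom, 283 with total counts and 225 with fly scaling. Apart from the target genes, they were picked by their calls in the main fit. High shares were therefore favoured in advance and do not measure how stable the calls are in general. In a fit of the line alone 229 were the same and 62 weaker. Under fly scaling 89 dropped below the threshold and RPL22 in SPT6-AID cells at 6 h reversed to -0.0788. Of the called lists, 25 were the same and 20 weaker by fry. Over the leave-outs 3015 gene results were the same and 777 weaker. For called lists 507 were the same, 31 weaker and 2 reversed, both for SPT6-AID 2h against 0h, list G2/M, whose camera adjusted p ran from 9.53e-05 to 0.863 (0.793 without SPT6-AID 0h replicate 2, 0.863 without 2h replicate 1).

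Gene counts moved far more. Leaving out 1 library gave 7 to 143 genes for SPT6-AID 2h against 0h, 3189 to 5310 for 6h, 0 to 37 for PAF1-AID 2h against 0h, 362 to 2439 for 6h, 1119 to 3183 for SPT6-AID 6h against 2h, 0 to 267 for PAF1-AID 6h against 2h, 0 to 7 and 30 to 1061 for the differences between lines at 2 h and 6 h, and 0 to 3 between lines at 0 h. Total counts gave 66 for SPT6-AID 2h, 79 for PAF1-AID 6h against 2h, 223 for the 6 h difference and 0 between lines at 0 h. Fly scaling gave 33 (SPT6-AID 2h), 2 (PAF1-AID 2h), 0 (PAF1-AID 6h against 2h), 4 and 16 (differences at 2 h and 6 h) and 0 (lines at 0 h). No filter gave 380, 274, 663, 34, 1330 and 317 for SPT6-AID 2h, PAF1-AID 2h, PAF1-AID 6h against 2h, both differences and the lines at 0 h. DESeq2 gave 470, 248, 781, 48, 1293 and 79 for the same comparisons. A mean of at least 1 CPM gave 457 for the 6 h difference, and limma-voom gave 4 for the 2 h difference. The line alone, with fewer libraries to estimate spread, gave 8 (SPT6-AID 2h), 0 (PAF1-AID 2h), 1940 (SPT6-AID 6h against 2h) and 101 (PAF1-AID 6h against 2h). The unadjusted counts beside each 0 of edgeR stand with its comparison.

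With the replicate number as a block the counts were 1613 and 10683 (SPT6-AID 2h and 6h), 1452 and 7958 (PAF1-AID 2h and 6h), 8466 and 4172 (6h against 2h), and 240 and 4513 (differences). Libraries sharing a number deviated from their groups alike, with r of 0.571 to 0.660 in SPT6-AID and 0.491 to 0.527 in PAF1-AID cells across genes, but the labels do not say what the number stands for.

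The correlation of the lines at 2 h was 0.0691 with no filter, 0.598 with a mean of at least 1 CPM, 0.395 with a prior count of 2 and 0.163 to 0.346 over leave-outs. At 6 h it was 0.264 with no filter and 0.430 to 0.628 over leave-outs. Between 2 h and 6 h it was 0.511, 0.667 and 0.647 with those settings and 0.426 to 0.774 over leave-outs in SPT6-AID cells. In PAF1-AID cells it was 0.537 with no filter, 0.775 with a mean of at least 1 CPM and 0.463 to 0.824 over leave-outs. The correlation with gene length was -0.0683 (SPT6-AID 2h) and -0.105 (6h) with no filter and -0.281 (6h) with a mean of at least 1 CPM. Over leave-outs it ran from -0.144 to -0.0556, from -0.223 to -0.155 and, for PAF1-AID 2h, from -0.0935 to 0.0371, turning to 0.0371 without 0h replicate 3 and to 0.0109 without 2h replicate 4.

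Lists passing camera numbered 0 with an estimated correlation in all 4 comparisons with 0 h. By fry they were 7 (SPT6-AID 2h) and 2 (PAF1-AID 2h), with the block 10 (PAF1-AID 6h), and over leave-outs 7 to 11 for PAF1-AID 2h (11 without 0h replicate 4). At the real depth, spread and number of libraries, 36.0% of simulated 2-fold changes were found. Depth was not varied on its own.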

Other observations

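The tests of fly genes on their own were chosen only after the fly counts were seen, and the rest of this part uses lists and tests set beforehand. In SPT6-AID cells at 6 h, ATF4, a translation-stress transcription factor (-1.67), DDIT3 (-2.45), TRIB3 (-1.21) and XBP1 (-1.18) fell among 6 of 25 ATF4 and unfolded protein response genes (camera adjusted p = 0.272), and MVK (-1.77) and SQLE (-1.01), enzymes of the pathway, fell among 5 of 21 cholesterol genes (camera adjusted p = 0.179, fry adjusted p = 0.0483). Of 27 G1/S genes 9 fell, 10 adjusted over the list alone (camera adjusted p = 0.0339, adjusted p = 0.682 with an estimated correlation). WNT targets fell in 7 of 21 cases, also 7 adjusted over the list alone, with AXIN2 at -2.28, RNF43 at -2.24 and BMP4 at -1.98 (camera adjusted p = 0.0397, adjusted p = 0.306 with an estimated correlation). Of 18 snoRNA host genes 7 fell and 1 rose (8 and 2 adjusted over the list alone), SNHG17 at -1.79 (camera adjusted p = 0.0382, adjusted p = 0.598 with an estimated correlation). Replication-dependent histones, which lack poly(A) tails, rose in 4 of 47 cases and in 1 adjusted over the list alone (camera adjusted p = 0.000159, adjusted p = 0.426 with an estimated correlation).

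At 2 h smaller shifts passed camera. In SPT6-AID cells CLK4 (-1.27) and CLK1 (-0.96) fell, 2 of 23 splicing regulators and genes regulated by nonsense-mediated decay over all genes and adjusted over the list alone (camera adjusted p = 0.00797, adjusted p = 0.176 with an estimated correlation), and PPM1D, a p53 target, fell (-1.13), 1 of 24 or 2 adjusted over the list alone (camera adjusted p = 0.00982, adjusted p = 0.14 with an estimated correlation). ATF4 and unfolded protein response genes had a median of -0.25 with 1 lower, or 2 adjusted over the list alone (camera adjusted p = 0.00982, adjusted p = 0.6 with an estimated correlation). In PAF1-AID cells FOS, KLF10 (0.89) and 1 more immediate early gene rose, or 7 with 3 lower adjusted over the list alone, with a median of 0.19 that becomes -0.03 under fly scaling (camera adjusted p = 0.0312, adjusted p = 0.339 with an estimated correlation). No snoRNA host gene of 18 passed over all genes by edgeR, while 6 were lower adjusted over the list alone (median -0.36, camera adjusted p = 0.000238, adjusted p = 0.605 with an estimated correlation).

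Between 2 and 6 h of PAF1 depletion the lists past camera were G2/M genes, with 0 of 28 called and 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000107, adjusted p = 0.909 with an estimated correlation), and DNA repair genes, with 1 of 23 lower and 5 adjusted over the list alone (camera adjusted p = 1.65e-05, adjusted p = 0.909 with an estimated correlation).

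In PAF1-AID cells at 6 h ATF4 (-1.55) and DDIT3 (-2.13) fell too, SPATA18 (3.65) and CDKN1A (1.06), p53 targets, rose, and HES1, a Notch target, fell (-1.54). FAP, a fibroblast protease, rose by 6.68 in PAF1-AID and 3.86 in SPT6-AID cells, while the 7 fibroblast markers did not pass as a list in SPT6-AID cells (camera adjusted p = 0.113) or in PAF1-AID cells (camera adjusted p = 0.832), where their median was -0.16 and their mean 0.78. In PAF1-AID cells FAP and SPATA18 exceeded genes named as the largest rises, so they missed that rule (mean log2 CPM of at least 1, same direction in both libraries). The size of their changes is uncertain.

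Fly genes were tested on their own, scaled among themselves. Of 7258 genes the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 7 and 24 (SPT6-AID 2h and 6h), 2 and 11 (PAF1-AID 2h and 6h), 13 and 2 (6h against 2h), and 0 and 9 (differences between lines at 2 h and 6 h), with 335 at an unadjusted p under 0.05 for the first of these differences. No other tool was run on fly genes.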
